A study of Penicillium oxalicum with 114 samples.

How the data were processed

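The series holds 114 RNA-seq libraries of mycelium of the filamentous fungus Penicillium oxalicum, whose RNA was taken with TRIzol per the labels' protocols. The libraries fall into 33 groups by strain, medium and culture time. The wild type HP7-1 gave 6 libraries and the control strain Ku70, which lacks the KU70 gene, gave 48. The mutants were named after the gene deleted: dClrB (24 libraries), dPOX01167 (18), dPOX02968 (3), dPOX04420 (3) and dPOX07277 (9). A further 3 libraries came from OES1167, which carries extra POX01167 under its own promoter. AV stands for Avicel, a microcrystalline cellulose, and WA for wheat bran plus Avicel. Transferred cultures were moved as hyphae into new medium, with 2% carbon source except on WA, where the labels give no share, and cultures that were not transferred grew from spores for 72 h. One of the 3 Ku70 libraries counted as WA 12 h is labelled 13 h. The labels name all samples of a group only by a letter or number, so replicates may be technical, and p-values measure the spread between these samples. In a chi-square test of their counts over genes, 2 libraries of a group differed by more than counting noise in all 363 pairs tested. Some pairs came close to it, with chi-square per degree of freedom of 1.94 for Ku70 induced libraries 20 and 21 (up to 651 between others of that group) and 2.61 for HP7-1 on glucose F and S (up to 21.6). The number of independent cultures may therefore be smaller than n, and all libraries were kept.

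Each library came as a table of genes with an expected count, an estimated number of reads per gene that need not be whole, and an FPKM value, both computed by the authors per the file headers. A few tables of dPOX07277 also held TPM values made by the authors, per the file headers, which were not used. Per the submitters' processing notes, BWA 0.7.10-r789, Bowtie2 2.1.0, RSEM 1.2.12 and DESeq2 were used. Their roles, the genome build and the annotation were not given in the sources used here. The deposited expected counts were rounded to whole numbers, which moved at most 0.009% of a library's counts. The comparisons had been designed, before the data were examined, for FPKM with limma on log2(FPKM + 1). Since expected counts were deposited, edgeR's quasi-likelihood test on the rounded counts was used for every comparison of groups, and limma became an alternative. FPKM as deposited by the authors served for the correlations, which span media and strains.

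Gene IDs were used as the files give them. The files held 9863 IDs, of which 9834 start with POX. The other 29 took at most 0.067% of a library's counts. None of the IDs matched the 9964 genes of the reference table (0 matches), so genes are named by ID only, with no product names and no coordinates. All 9834 lengths are multiples of 3 (100%), hence coding lengths. How the authors' counting treated reads shared by similar or overlapping genes was not given in the sources used here, so such genes are uncertain.

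The tables are of 3 kinds. A shallow kind totals 365937 to 4242956 expected counts per library in 30 libraries of 9 groups. A deep kind totals 13277742 to 14731797 counts in 36 libraries of 9 groups. The time-course kind totals 5368155 to 8267079 counts in 48 libraries of 16 groups. In it 77.1% to 81.3% of the counts above 0 are whole, against at least 98.2% in the other kinds, and 67 IDs stand at 0 in all 48 libraries but average over 1 CPM in both other kinds. Within the time-course kind, the FPKM per count of 3835 genes with over 100 counts parts the libraries into 3 quantification sets. Mean differences were at most 0.131 within a set and at least 0.149 between sets (log2). Each of the 16 groups has 1 library in each set, and the letters F, S and T name the sets in 33 of 33 lettered libraries.

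Genes with a mean of at least 1 CPM over the libraries of a fit were tested, with TMM scaling. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, two-sided. The 45 time-course libraries of Ku70, dClrB and dPOX01167 shared 1 fit. Each 24 h group compared with the 24 Ku70 libraries on an inducing carbon source had a fit of its own with them (27 libraries). For comparisons among the fatty-acid groups, their 18 libraries shared 1 fit. No replicate block was used. Same-set libraries of compared time-course groups deviated together, with correlations of 0.57 to 0.95, each library best with its own set. The pairing by set was found from the values, not the labels, and blocked counts stand beside those they moved by over 1.5 times. Letters paired dPOX07277 libraries on arachidonic acid oil and linolenic acid (0.15 to 0.42) and no other groups outside the time course. Levels are plain CPM of the library total, as mean ± SD.

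A pair of gene lists, 9 cellulase genes and 4 xylanase genes, was fixed by IDs known from the study group's earlier publications. Lists by product name, among them transcription factors and conidiation markers, had been planned too and could not be made without names. Each list was tested against all other genes with limma's camera, with a preset correlation of 0.01 and with the correlation estimated. The deleted gene and list members may be named in any comparison. Of other IDs, at most 2 rose and 2 fell per account: those with the largest change among called genes whose groups did not overlap, taken from the comparison with most calls. The account of dPOX01167 on WA departs from this and names IDs from each of its times, among them POX01168, picked after its values were seen. IDs at 0 in only some quantification sets were passed over. A fold against a group at 0 in every library is a lower bound, from 3 counts per library. Intervals are 95% intervals, and they and floors cover counting error and the fitted spread of these libraries only.

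For the correlations, a list's score is the mean log2(FPKM + 1) of its members, without the gene correlated with it. Group means of 8715 genes were used, with Pearson's r, Spearman's rho and 100000 permutations, or exact permutations in sets of under 10 groups. A gene was called at r of at least 0.8 and an adjusted p under 0.05. The permutations treat groups as exchangeable, although groups share strains, media and kinds of table, so their p-values may be too small. Groups were taken as separate clusters where the largest gap in the score was at least 2 times the next.

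The tests were first run on simulated counts with 200 changed genes. Of genes changed 2-, 4- and 8-fold, 31.3%, 76.1% and 90.9% were called with the depths of dClrB against Ku70 on AV at 12 h (8140 genes). The shares were 23.9%, 79.1% and 93.9% for HP7-1 (8526 genes), 28.4%, 86.6% and 89.4% for dPOX02968 (8541 genes), and 37.3%, 94% and 97% for dPOX07277 on arachidonic acid oil (8484 genes). They were 9%, 62.7% and 83.3% for the cultures not transferred (8474 genes) and 13.4%, 56.7% and 69.7% for the difference of the dClrB effect between media (8140 genes). The simulated libraries were drawn independently around a common mean per gene, without kinds of table or quantification sets. The shares therefore hold for independent libraries and do not cover the structure of the real ones.

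The lists, groups, comparisons, thresholds and most alternatives were fixed before the data were examined. Alternatives were median-ratio size factors, no filter, limma on log2(FPKM + 0.1) and log2(FPKM + 1), DESeq2, fits of the compared groups alone, other choices of Ku70 controls, replicate blocks, and leaving out each library in turn. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.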

Results

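The series asks which genes have transcript levels that follow the cellulase and xylanase genes when Penicillium oxalicum, a fungus that secretes enzymes against plant cell walls, meets other carbon sources or loses a regulator gene. RNA-seq gave expected counts for 114 libraries in 33 groups. HP7-1, the wild type, was grown for 72 h without transfer on glucose (n = 3) and on wheat bran, wheat bran plus bagasse and wheat bran plus rice straw (n = 1 each). The Ku70 strain, in which genes are easily deleted and which served as control, was grown on AV at 12 and 36 h, on WA at 12, 24 and 36 h (n = 3 each), and for 24 h on an inducing carbon source (n = 24) or on AV with arachidonic acid oil, linolenic acid or oleic acid (n = 3 each). All mutant groups held 3 libraries. Totals were 365937 to 902988 counts per library for HP7-1 on glucose and 705723, 752903 and 3115003 for its wheat bran, bagasse and rice straw libraries. They were 5368155 to 8267079 in the time course and 2131649 to 14731797 among the Ku70 induced libraries. Fatty-acid groups, OES1167 and dPOX02968 had 13277742 to 14627510. All p-values below come from edgeR with Benjamini-Hochberg adjustment unless another test is named, levels are in CPM (mean ± SD), and list tests are camera's.

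The targeted genes were looked at first. POX02968 was at 0.211 to 0.359 CPM in dPOX02968 and at 30.1 CPM or more in all other libraries. POX04420 was at 0 in dPOX04420 and at 17.3 CPM or more elsewhere, and POX07277 was at 0 in dPOX07277 and at 19.4 CPM or more elsewhere. No locus is named for clrB in the labels. POX01167 was at 0 in the 3 dPOX01167 libraries that were not transferred and at 0.791 CPM or less in the 9 on WA. On AV the label was borne out only in library T at 12 h. Levels were 1603, 25.4 and 0 CPM in libraries F, S and T at 12 h and 95.6, 207 and 153 CPM at 36 h. The AV libraries are therefore called the libraries labelled dPOX01167 throughout. In OES1167 POX01167 stood at 394 to 428 CPM, above the 118 to 342 CPM of the 24 Ku70 induced libraries. On AV, levels of POX01167 differ between the quantification sets, as in Ku70 at 36 h (1214, 1236 and 157 CPM), where the effective length of the gene was 514, 489 and 2014.

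**Figure D1:**
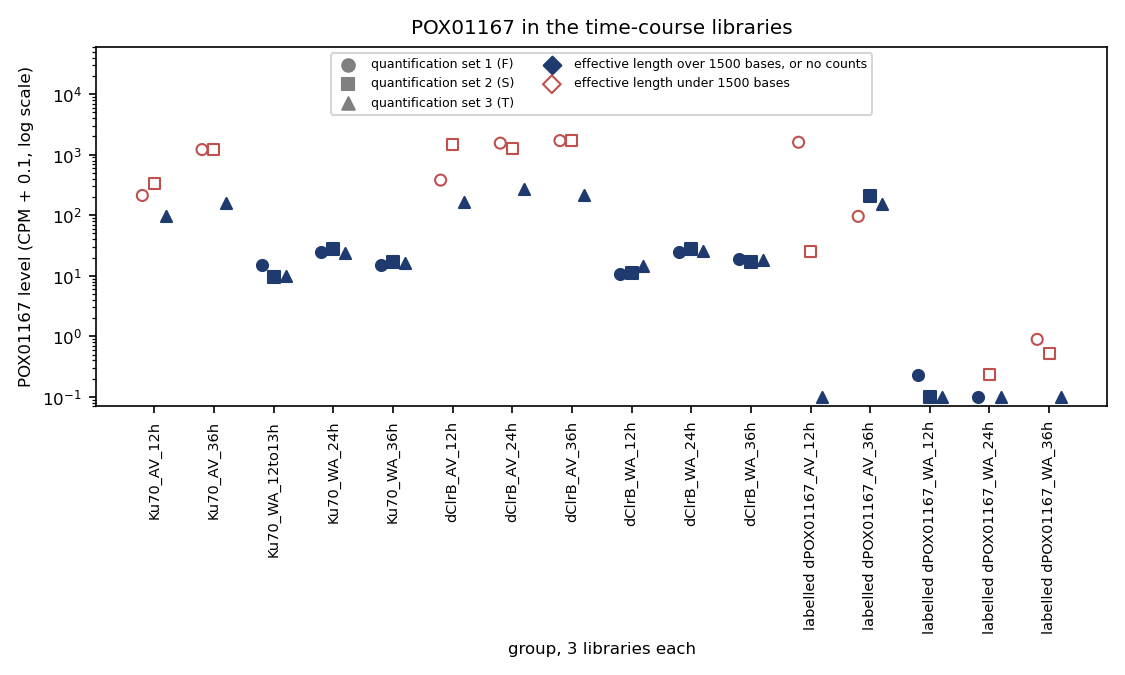
POX01167 level (CPM + 0.1, log scale) in each time-course library by group, with 1 marker shape per quantification set and open red markers for short effective lengths. The libraries labelled dPOX01167 on AV reach 1603 CPM, while those on WA stay at 0.791 CPM or less.

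In HP7-1, wheat-bran media raised 8 of the 9 cellulase genes and 4 of the 4 xylanase genes over glucose (medians 5.38 and 6.65, log2). The largest rises among the cellulase genes were those of POX07535 (7.80, SE 0.49, 725 ± 211 against 2.49 ± 0.26 CPM) and POX02740 (6.21, SE 1.12). POX04786 rose by 6.04 (SE 0.65), from 27.5 ± 16.3 to 2139 ± 1078 CPM. Of the xylanase genes, POX08990 rose most (9.37, SE 0.84, 662-fold), followed by POX00063 (8.18, SE 0.94). POX06835 differed by 0.15 (SE 0.44, adjusted p = 0.833). Both lists stood above the other genes (adjusted p = 6.42e-15 and 4.77e-10, and adjusted p = 0.0275 for each with an estimated correlation), and adjusted over the list alone the same 8 and 4 members were called. Outside the lists POX02284 was at least 51.0-fold higher and POX09801 at least 23.7-fold higher on wheat-bran media, while POX07865 and POX02605 were lower (-11.95 and -11.81). Of 8526 genes, 981 were higher and 899 lower on wheat-bran media. The spread includes the 3 media, and without the bagasse library 1240 genes were called in place of 1880.

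In Ku70, cellulase genes stood far lower on WA than on AV. At 12 h 7 of 9 fell (median -5.41), among them POX04786 (fell by 10.42, SE 1.59, 1.12 ± 0.977 against 1726 ± 682 CPM), POX01166 (fell by 10.08, SE 0.71) and POX05587 (fell by 7.97, SE 0.75). At 36 h 6 of 9 fell (median -2.95), with POX05587 and POX04786 at -7.75 and -7.64. Of the xylanase genes, POX00063 and POX08484 fell at 12 h (-3.68 and -3.27) while POX08990 rose (2.04, SE 0.38), and POX00063, POX06783 and POX08484 fell at 36 h (-3.02, -3.14 and -4.84). The cellulase list stood below the other genes at 12 h (adjusted p = 6.36e-07, and adjusted p = 0.0391 with an estimated correlation), whereas the xylanase list did not pass (adjusted p = 0.39). At 36 h both lists stood below, with adjusted p = 0.0315 for each with an estimated correlation. The summed level of the 9 cellulase genes was 8753 ± 1928 CPM on AV and 479 ± 142 CPM on WA at 12 h, and 12121 ± 1596 against 563 ± 47 CPM at 36 h. POX00062 and POX00227 were at least 77.2-fold and 66.1-fold higher on WA at 12 h, POX01177 fell by 13.95 and POX04499 was at least 308-fold lower. On WA, 1070 genes were higher and 1249 lower at 12 h, and 778 and 823 at 36 h.

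With time on AV, 539 genes were higher and 389 lower at 36 h than at 12 h in Ku70. None of the 9 cellulase genes passed (edgeR 0, with 0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma), and 1 of 4 xylanase genes, POX08990, fell (-1.11, SE 0.37), but 0 did with edgeR without Ku70 library 24, 25, 26 or 27. On WA, 1137 were higher and 819 lower at 36 h. There 5 cellulase genes rose, among them POX06835 (4.01, SE 0.52) and POX04786 (3.74, SE 1.23), and POX07535 and POX03641 fell (-1.20 and -1.57), only 1 of them without library 29, 30 or 37. The cellulase list as a whole stood above the other genes with time on WA (adjusted p = 0.0341, and adjusted p = 0.254 with an estimated correlation). Of the xylanase genes POX08990 fell by 3.27 (SE 0.40), and 2 fell without library 36.

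Loss of clrB, a gene known as an activator of cellulase genes in filamentous fungi, lowered 7 of 9 cellulase genes on AV at both times and 4 of 4 xylanase genes at 12 h and 3 of 4 at 36 h. At 12 h POX05570 fell 265-fold (-8.05, SE 0.73), POX05571 211-fold (-7.72, SE 0.67), POX04786 198-fold (-7.63, SE 1.40, 8.49 ± 7.39 against 1726 ± 682 CPM) and POX01166 194-fold (-7.60, SE 0.64). At 36 h POX04786 fell by 8.14 (SE 1.43), and POX01166 and POX05587 fell too (-7.28 and -6.85). POX02740 and POX06835 were not called at either time (0.94 and 0.24 at 12 h, -0.17 and 0.60 at 36 h). Of the xylanase genes POX08484 fell at both times (-5.66 at 12 h and -3.16 at 36 h), as did POX00063 (-3.86 and -3.31), while POX08990 was called only at 12 h (-1.88). Medians were -6.08 and -3.36 (log2) for the cellulase and xylanase genes at 12 h, and -5.93 and -3.23 at 36 h. Both lists stood below the other genes at both times (adjusted p = 9.13e-07 and 1.14e-06 at 12 h, 0.000587 and 0.000812 at 36 h, all with an estimated correlation), and adjusted over the list alone 7 and 4 members were called each time. Outside the lists, POX08486 was at least 125-fold higher in dClrB at 36 h. POX03097 was at least 193-fold higher there (59.6 to 91.3 CPM against 0), but Ku70 on AV at 12 h had 60.9 to 88 CPM of it, so that the Ku70 libraries at 36 h stand apart. POX03600 and POX00114 were at least 166-fold and 63.0-fold lower at 36 h. There were 131 genes higher and 111 lower at 12 h and 341 and 260 at 36 h, of 8140 tested, with 42 higher and 55 lower genes shared between the times where independent lists would share 5.49 and 3.55. At 12 h the count of 242 became 42 in a fit of the 2 groups alone (10 higher and 32 lower), 376 with libraries paired by quantification set, 156 without dClrB library T, and 138 or 147 without Ku70 library 24 or 25.

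On WA, where Ku70 itself had little cellulase transcript, loss of clrB lowered 1 of 9 cellulase genes at 12 h (POX03641, -3.02, SE 0.51), 1 at 24 h (POX05570, -2.44, SE 0.58) and 5 at 36 h. The 36 h members were POX05570 (-4.45, SE 0.62), POX05571 (-4.14), POX01166 (-3.86), POX05587 (-2.73) and POX03641 (-1.74). Of the xylanase genes, none was called at 12 or 24 h (edgeR 0, with 0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma each time), and POX08990 fell at 36 h (-1.83, SE 0.39). The cellulase list stood below the other genes at 12 and 36 h (adjusted p = 0.027 and 0.00202 with an estimated correlation) and at 24 h with the preset correlation (adjusted p = 4.38e-05) but not with an estimated one (adjusted p = 0.0892), and the xylanase list stood below at 36 h (adjusted p = 0.0222, and adjusted p = 0.0601 with an estimated correlation). Adjusted over the list alone, 3, 2 and 7 cellulase members were called. The difference between the media was tested at 36 h and was positive, meaning a weaker fall on WA, for 3 cellulase genes and 1 xylanase gene (list tests adjusted p = 0.0482 for both with an estimated correlation), with 321 genes higher and 329 lower in all. Counts were 17 higher and 17 lower at 12 h, 39 and 20 at 24 h and 118 and 97 at 36 h, and with the 2 groups alone 3, 19 and 136 in all, with paired libraries 71, 108 and 323 (977 for the difference between media, where 2 xylanase genes were called without dClrB library S on AV). The call of POX05570 at 24 h ended without any 1 of the 6 libraries, and at 36 h 3 cellulase genes fell without dClrB S. Single libraries moved the counts. At 12 h there were 20 without dClrB T and 21 or 18 without Ku70 29 or 31, at 24 h there were 37 without T and 28 or 29 without Ku70 33 or 34, and at 36 h there were 112 without S and 141 without Ku70 35.

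Moved to the inducing carbon source for 24 h, dClrB again had 6 of 9 cellulase and 3 of 4 xylanase genes lower than the 24 Ku70 libraries. POX04786 fell by 9.76 (SE 2.46, 20.4 ± 18.7 against 15078 ± 11094 CPM), and POX01166 and POX05570 fell too (-8.19, SE 2.09, and -7.41, SE 1.93). POX06783 fell by 5.68 (SE 1.52), and POX08484 (-4.67) and POX00063 fell as well. POX06835 was higher by just under the minimum (1.00, SE 0.26, adjusted p = 0.00835) and was not called. Medians were -6.96 and -4.58, with adjusted p = 0.00635 and 0.0289 for the lists, and adjusted p = 0.278 for both with an estimated correlation. Adjusted over the list alone 7 and 3 members were called. POX05569, next in the numbering to the cellulase genes POX05570 and POX05571, rose from 7.57 ± 3.03 to 4011 ± 2453 CPM (8.98, adjusted p = 5.05e-20), and POX09387 rose by 7.37, while POX07516 and POX02054 fell (-13.39 and -11.55). The growth protocol gives Avicel for 24 h for the inducing carbon source as well. The dClrB libraries labelled AV, of another kind of table, had POX05569 at 0 CPM at 24 h and 6.19 to 9.27 CPM at 36 h. Ku70 on AV at 36 h had 0 CPM of it in each library. A rise to the level on the inducing carbon source was thus not seen on AV. At 36 h dClrB still stood above Ku70 there, at a far lower level. In all 742 genes were higher and 284 lower (711 and 564 with DESeq2, 386 and 305 with the 3 controls of set 1, which share 427 of the calls), and without dClrB library F 442 were called in place of 1026. Of the listed genes, without F 1 cellulase gene was lower and 1 higher and 0 xylanase genes were called with edgeR, and without S or T 1 xylanase gene was lower. Of the 1026, 181 higher and 67 lower genes were shared with AV at 36 h, where independent lists would share 28.6 and 8.59.

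The dClrB libraries on AV at 24 h have no Ku70 partner of their own time and were set against the Ku70 induced libraries, whose tables are of other kinds, so strain and kind of table cannot be told apart. There 7 cellulase and 4 xylanase genes were lower (medians -7.90 and -5.25), POX04786 by -11.42 (SE 2.76) and POX05587 by -9.73 (SE 2.52). The lists did not stand apart from the other genes (adjusted p = 0.105 and 0.158, and adjusted p = 0.473 for both with an estimated correlation), beside 1261 genes higher and 1520 lower. Without any 1 of the dClrB libraries 2 xylanase genes were lower.

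**Figure D2:**
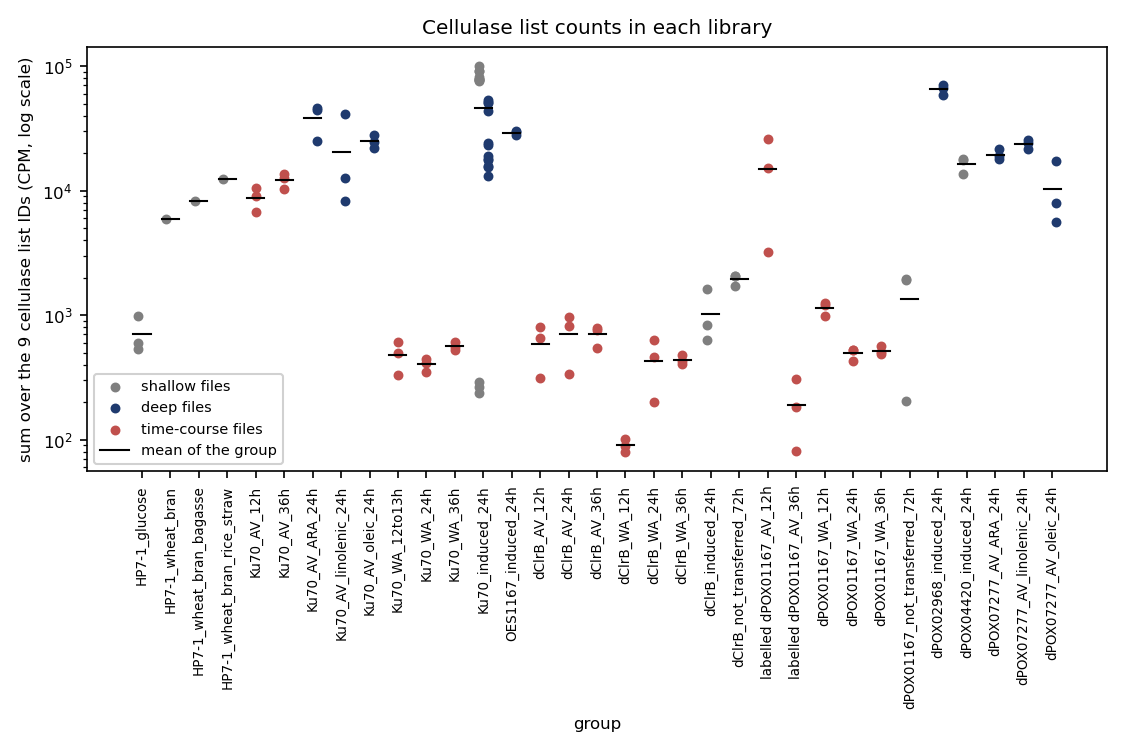
Summed level of the 9 cellulase genes (CPM, log scale) in each of the 114 libraries by group, with points coloured by kind of table and a line at the group mean. Among the Ku70 induced libraries, 3 lie at 236 to 290 CPM and the other 21 at 13149 to 99559 CPM. Of these 21, the 9 shallow ones lie at 75918 to 99559 CPM and the 12 deep ones at 13149 to 53517 CPM.

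The libraries labelled dPOX01167 on AV at 36 h had 8 of 9 cellulase genes and 4 of 4 xylanase genes below Ku70. POX04786 was at 4.29 ± 1.59 against 3370 ± 819 CPM (fell by 9.62, SE 1.52), POX05587 fell by 9.16 (SE 0.79), and POX01166 and POX05570 fell too (-9.02, SE 0.68, and -8.05). POX08484 and POX06783 fell (-5.98, SE 0.92, and -4.72). POX02740 was not called (-4.05, adjusted p = 0.0597). Medians were -6.10 and -3.77, with adjusted p = 0.0151 and 0.0188 with an estimated correlation, and adjusted over the list alone 9 and 4 members were called. At 12 h the same label gave POX05587 higher (2.83-fold), and POX06835 (-1.33) and POX08990 (-1.10) lower, with no shift of the lists (adjusted p = 0.603 and 0.364). There the median and mean of the cellulase genes were positive while the list test pointed down. Outside the lists POX04532 (380 ± 121 CPM against 0) was at least 913-fold higher at 36 h, POX01421, which fell from 12 to 36 h in Ku70 on AV, at least 85.8-fold higher and POX02423 at least 492-fold lower. Totals were 750 higher and 646 lower at 12 h, and 782 and 1262 at 36 h. All these directions come from libraries that hold POX01167, except T at 12 h. The 3 calls of listed genes at 12 h were also unstable, with 0 cellulase genes called by edgeR without library T or Ku70 25, and 0 xylanase genes without S or Ku70 24. At 12 h 847 genes were called without library S and 112 with the 2 groups alone. Library T alone, which had no POX01167 counts, has no spread of its own, so calls from it are not given.

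On WA, where POX01167 was absent from the mutant, few genes differed. POX01168, which follows POX01167 in the numbering, rose at 12 h (3.47, 11.1-fold, 23.4 against 2.05 CPM) and at 24 h (2.66, 6.31-fold). POX05588 fell at 12 h by 3.81, POX00142 at 24 h by 1.90 and POX09364 at 36 h by 7.35. The largest rises at 36 h were those of POX02794 (at least 13.9-fold) and POX01424 (at least 11.5-fold). Calls were 3 higher and 14 lower at 12 h, 3 and 3 at 24 h, and 18 and 11 at 36 h. None of the 13 listed genes was called by edgeR (0 of 9 and 0 of 4 at each time). At an unadjusted p under 0.05 there were 1, 0 and 1 cellulase genes and 0, 0 and 1 xylanase genes at 12, 24 and 36 h, and 0 with DESeq2 or limma at any time. At 36 h the xylanase list stood above the other genes (median 0.82, adjusted p = 0.00199, and adjusted p = 0.0172 with an estimated correlation), and 1 member was called adjusted over the list alone. The difference between WA and AV at 36 h, which includes the doubtful AV libraries, covered 7 cellulase and 4 xylanase genes (list tests adjusted p = 0.0026 for both with an estimated correlation), with 1011 genes higher and 652 lower. With paired libraries 34, 15 and 49 genes were called at 12, 24 and 36 h in place of 17, 6 and 29, and with the 2 groups alone 0, 0 and 4. At 12 h there were 9 or 11 without mutant library S or T and 30 or 11 without Ku70 29 or 31, and at 36 h 18 without F and 11 or 16 without Ku70 36 or 37.

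Besides HP7-1, only dPOX01167 and dClrB were sampled from cultures grown from spores for 72 h without transfer. No Ku70 group was, so these mutants were compared with each other. POX01167 was at least 217-fold lower in dPOX01167. Of the cellulase genes, POX02740 (fell by 6.14, SE 0.42) and POX06835 (fell by 6.63, SE 0.26, 15.9 ± 1.63 against 1408 ± 79.5 CPM) were lower in dPOX01167. Of the xylanase genes, POX00063 and POX08484 were lower (-2.01 and -2.48). The cellulase genes had a median of 1.06 and a mean of -0.35, and neither list passed (adjusted p = 0.44 and 0.273). POX05173 and POX01152 rose by 8.44 and 7.95 relative to dClrB, and POX04276 fell by 10.42 (2.93 ± 1.4 against 3662 ± 414 CPM). In all 1548 genes were higher and 1496 lower in dPOX01167. Without dPOX01167 library S 6 cellulase genes were higher and 2 lower, and without dClrB library F or T 1 xylanase gene was lower.

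In dPOX02968, no listed gene was called against the Ku70 induced libraries (edgeR 0 of 9 and 0 of 4, with 0 and 1 at an unadjusted p under 0.05 and 0 with DESeq2 or limma). The xylanase median was 1.12, and the list test passed (adjusted p = 0.0271) but not with an estimated correlation (adjusted p = 0.38 with an estimated correlation). POX08990 differed by 2.15 (95% interval 0.26 to 4.05, adjusted p = 0.183). POX01925 and POX01924 fell (-9.19 and -9.10), the latter to 1.79 ± 0.395 against 987 ± 299 CPM, and POX07664 rose by 2.49. Calls were 83 higher and 46 lower, but 108 and 307 with DESeq2 and 187 and 271 with controls of the same kind of table, and 28, 27 or 47 without library F, S or T, 221 without the Ku70 libraries 8 to 10. With only the 3 Ku70 libraries of set 1 (F, S and T) as controls, 1 cellulase gene was lower and 2 xylanase genes were higher (1196 calls). These 3 are tables of the shallow kind and those of dPOX02968 of the deep kind. The summed cellulase genes stood at 58929 to 70115 CPM in dPOX02968, below these 3 (76973 to 78091 CPM) but above all deep Ku70 induced libraries (13149 to 53517 CPM). The summed xylanase genes stood at 13459 to 14926 CPM against 1265 to 13632 CPM in those deep libraries. These sums were not tested. In libraries 8 to 10 the summed cellulase genes were at 236 to 290 CPM, against 13149 to 99559 CPM in the other 21, and the xylanase genes at 122 to 159 against 1265 to 13632 CPM. Of these 21, the 9 shallow libraries held 75918 to 99559 CPM of cellulase genes and the 12 deep ones 13149 to 53517 CPM. The control strain itself thus differed between kinds of table without overlap. The same controls enter every comparison with the Ku70 induced libraries.

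In dPOX04420 again no listed gene was called (edgeR 0 of 9 and 0 of 4, with 2 of each list at an unadjusted p under 0.05, 2 of each with DESeq2 and 0 with limma). Medians were -1.58 and -2.85, with adjusted p = 0.0377 for both lists, and adjusted p = 0.445 and 0.44 with an estimated correlation. Adjusted over the list alone, POX06835 (-1.05, SE 0.29) and POX00063 (-4.42, SE 1.56) were called. POX04420 was at least 107-fold lower, POX09299 fell by 4.72, and POX03448 and POX09621 rose by 3.42 and 3.40. Calls were 73 higher and 65 lower, but 97 and 218 with DESeq2, and 54, 9 or 20 without library F, S or T, 275 without the Ku70 libraries 8 to 10 (131 higher and 144 lower). With the remaining controls of the same kind of table as dPOX04420, 1001 genes were called, among them 9 of 9 cellulase and 4 of 4 xylanase genes lower, and with those of set 1 (1487 calls) the same numbers of listed genes were lower.

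OES1167 had 15 genes higher and 3 lower than the 24 Ku70 libraries, but 32 higher and 88 lower with DESeq2, and 1 call when any of its 3 libraries was left out (84 without the Ku70 libraries 8 to 10). POX05007 fell by 12.95 (0.0942 against 840 CPM), POX06231 rose by 2.09 and POX01673 by 1.98. No listed gene was called (edgeR 0 of 9 and 0 of 4, with 1 and 0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma). Medians were -0.51 and -0.69, while the list tests, which did not pass, pointed up. With only the 3 controls of set 1, which are of another kind of table, 1828 genes were called, among them 8 cellulase and 2 xylanase genes, all lower. The summed cellulase genes stood at 28131 to 30325 CPM in OES1167 and 76973 to 78091 CPM in these controls. The deep Ku70 induced libraries had 13149 to 53517 CPM. Strain and kind of table therefore cannot be told apart with the set 1 controls.

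POX07277 was deleted only in cultures on AV with a fatty acid or oil, at doses not given in the labels, and each was compared with Ku70 on the same addition. On arachidonic acid oil 4 cellulase genes fell, among them POX07535 (-3.76, SE 0.62), POX02740 (-2.05, SE 0.47) and POX03641 (-2.03, SE 0.43), and 4 of 4 xylanase genes fell, led by POX08484 (-2.68, SE 0.70) and POX06783 (-2.38). POX06835 rose there (1.21, SE 0.30), on linolenic acid (1.95, SE 0.31) and on oleic acid (1.70, SE 0.30). On linolenic acid POX02740 (1.74) and POX08990 (1.06) rose too and no listed gene fell. On oleic acid POX04786 (-2.10), POX05570 (-1.38), POX05571 (-1.33) and POX03641 (-1.13) fell and POX08990 rose (1.67, SE 0.29). On the oil both lists stood below the other genes (medians -1.25 and -2.23, adjusted p = 0.022 and 0.0175, and adjusted p = 0.347 for both with an estimated correlation), and adjusted over the list alone 6 fell and 1 rose, and 4 fell. The xylanase median was negative while the list test pointed up on linolenic and on oleic acid. POX07277 was at least 142-fold, 93.3-fold and 103-fold lower on the oil, linolenic and oleic acid, and POX07559 and POX09470 rose by 9.42 and 8.92 on oleic acid. Of 8484 genes, 692 were higher and 531 lower on the oil, 792 and 460 on linolenic acid, and 1901 and 889 on oleic acid. The oil and linolenic acid comparisons shared 518 higher and 269 lower genes, where independent lists would share 64.6 and 28.8. Linolenic and oleic acid gave different effects of the deletion for 316 genes upward and 1177 downward, of the listed genes POX05570 (1.39). Called members rested on single libraries in places. On linolenic acid 1 cellulase gene rose without Ku70 41, and of the xylanase genes 0 rose with edgeR without Ku70 42 or mutant F and 2 without Ku70 43. On oleic acid 2 cellulase genes fell without mutant T.

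Against the 24 Ku70 induced libraries, no listed gene was called in Ku70 on the oil or on either fatty acid (edgeR 0 on each). On the oil 0 were under an unadjusted p of 0.05 and 0 were called by DESeq2 or limma. On linolenic and on oleic acid 1 cellulase gene and 2 xylanase genes were under it, the same numbers were called by DESeq2, all as lower, and 0 by limma. On the oil, medians of both lists were negative while the list tests pointed up. POX09284 and POX06231 rose by 3.75 and 2.76 on oleic acid, and POX08108 and POX08694 fell (-8.09 and -7.88). There were 11 genes higher and 6 lower on the oil, 134 and 86 on linolenic acid, and 129 and 171 on oleic acid. The balance turned on the oil and linolenic acid, with 26 higher and 293 lower and 158 and 482 with DESeq2, 86 and 331 and 201 and 513 with controls of the same kind of table, and 34 and 91 and 193 and 267 without the Ku70 libraries 8 to 10. On oleic acid it turned the other way with no filter (164 and 143). Without libraries 38, 39 or 40 the oil had 4, 5 or 5 calls, without 41, 42 or 43 linolenic acid had 61, 51 or 106, and without 44, 45 or 46 oleic acid had 54, 39 or 53. In all, the counts without the Ku70 libraries 8 to 10 were 125, 460 and 597. With only the 3 controls of set 1, which are of another kind of table, 4 cellulase genes and 1 xylanase gene were lower on the oil, 8 and 3 on linolenic acid and 7 and 3 on oleic acid, with 1198, 1702 and 1522 calls in all. Summed cellulase genes stood at 76973 to 78091 CPM in these controls and 13149 to 53517 CPM in the deep Ku70 induced libraries. Addition and kind of table therefore cannot be told apart with the set 1 controls.

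Linolenic and oleic acid have chains of equal length, and linolenic acid has more double bonds. Compared directly in Ku70 at 24 h, they differed for 14 genes, 8 higher and 6 lower on linolenic acid. POX09284 was at 1.69 against 187 ± 32.3 CPM (fell by 6.80), and POX06595 and POX00310 rose by 2.72 and 2.70. No listed gene was called (edgeR 0, with 0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma), and 95% intervals of the differences ran from -1.71 to 1.15 over the cellulase genes and from -1.58 to 1.48 over the xylanase genes. The linolenic libraries disagreed. Summed cellulase genes were at 12549, 8182 and 40880 CPM in libraries 41, 42 and 43, against 22125 to 27700 CPM on oleic acid. The lack of calls therefore does not show equal levels. The cellulase list test passed (adjusted p = 0.0111) but not with an estimated correlation (adjusted p = 0.506 with an estimated correlation), and for the xylanase genes the median was positive and the test pointed down. The count was 5, 4 or 18 without library 41, 42 or 43, and 5, 5 or 7 without 44, 45 or 46.

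Arachidonic acid oil differed from both acids in Ku70. POX07535 was higher on the oil than on oleic acid (3.66, SE 0.61) and than on linolenic acid (3.77, SE 0.62), at 88.8 ± 70.8 against 6.88 ± 1.94 and 6.48 ± 0.536 CPM. POX08990 was higher too (2.82, SE 0.30, and 2.76, SE 0.30), POX06783 against oleic acid (2.27, SE 0.57) and POX02740 against linolenic acid (2.09, SE 0.47). The cellulase list test gave adjusted p = 0.208 and 0.0452 and the xylanase list test adjusted p = 0.0276 and 0.0197, against oleic and linolenic acid, with an estimated correlation. Adjusted over the list alone, 2 cellulase and 3 xylanase genes were called against oleic acid, and 3 and 3 against linolenic acid. POX06601 and POX09085 rose by 5.57 and 4.32 against linolenic acid, and POX08108 and POX03935 fell (-4.48 and -4.43). Against oleic acid 98 genes were higher and 33 lower, and against linolenic acid 101 and 87. Of the listed genes, 0 cellulase genes were higher than on oleic acid without library 46 (edgeR) and 1 xylanase gene without 39, 40, 44, 45 or 46. Against linolenic acid 1 cellulase gene was higher without 39, 40, 41 or 42 and 6 without 43, and 2 and 4 xylanase genes without 38 and 43. Without library 38, 40, 44, 45 or 46 the first count was 262, 39, 57, 60 or 20, and without 38, 39, 40, 41 or 42 the second was 348, 100, 44, 80 or 54.

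In dPOX07277, linolenic against oleic acid gave 167 genes higher and 1107 lower, among the listed genes POX04786 (1.56, SE 0.56) and POX05570 (1.13, SE 0.33), and none of the xylanase genes (edgeR 0, with 0 at an unadjusted p under 0.05 and 0 with DESeq2 or limma), whose 95% intervals ran from -1.51 to 1.74. The oil against oleic acid gave 298 and 1163, POX08824 and POX05467 falling (-4.83 and -4.81) and POX03095 and POX07378 rising by 2.93 and 2.62. The oil against linolenic acid gave 22 and 27. Neither of these changed a listed gene (edgeR 0). Of the cellulase genes 2 were under an unadjusted p of 0.05 in each, 1 was called by DESeq2 in each and limma called 1 against oleic acid and 0 against linolenic acid, while these numbers were 0 for the xylanase genes. Intervals ran from -2.08 to 2.17 and -1.86 to 1.91 against oleic acid, and from -2.68 to 1.52 and -1.90 to 1.62 against linolenic acid, for cellulase and xylanase genes. The cellulase list stood lower on the oil than on linolenic acid (adjusted p = 0.0453, and adjusted p = 0.693 with an estimated correlation), and POX02740 was called adjusted over the list alone (-1.69). Counts rested on single libraries of the mutant. Linolenic against oleic acid had 763 without linolenic S and 362 or 2672 without oleic F or S, the oil against oleic acid had 592 or 2634 without oleic F or S, and the oil against linolenic acid had 27, 14 or 12 without oil library F, S or T and 20, 27 or 22 without linolenic F, S or T. Of the cellulase genes, those higher on linolenic than on oleic acid numbered 1 without linolenic F or T, 0 with edgeR without linolenic S or oleic F or T, and 6 without oleic S, and 4 were higher on the oil than on oleic acid without oleic S. Fitted alone, both comparisons with oleic acid had 0 calls with edgeR.

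**Figure D3:**
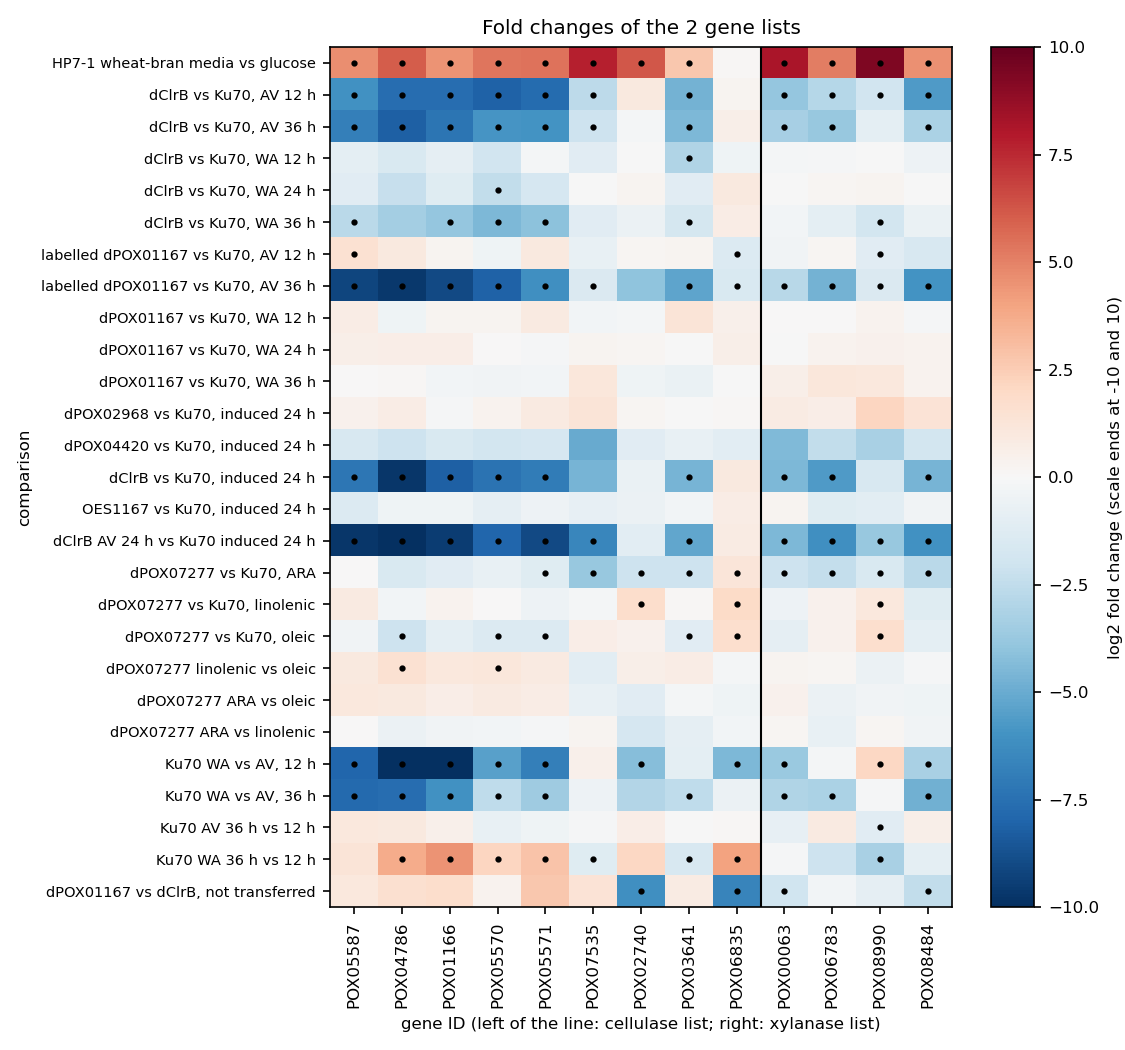
Log2 fold change (colour, blue lower and red higher in the first group, scale ending at -10 and 10) of the 9 cellulase and 4 xylanase genes (columns) in the comparisons of mutants, media and times (rows), with a dot where the gene was called. The deepest blue lies in dClrB on AV and on the inducing carbon source, in the libraries labelled dPOX01167 on AV at 36 h, and in Ku70 on WA against AV.

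**Figure D4:**
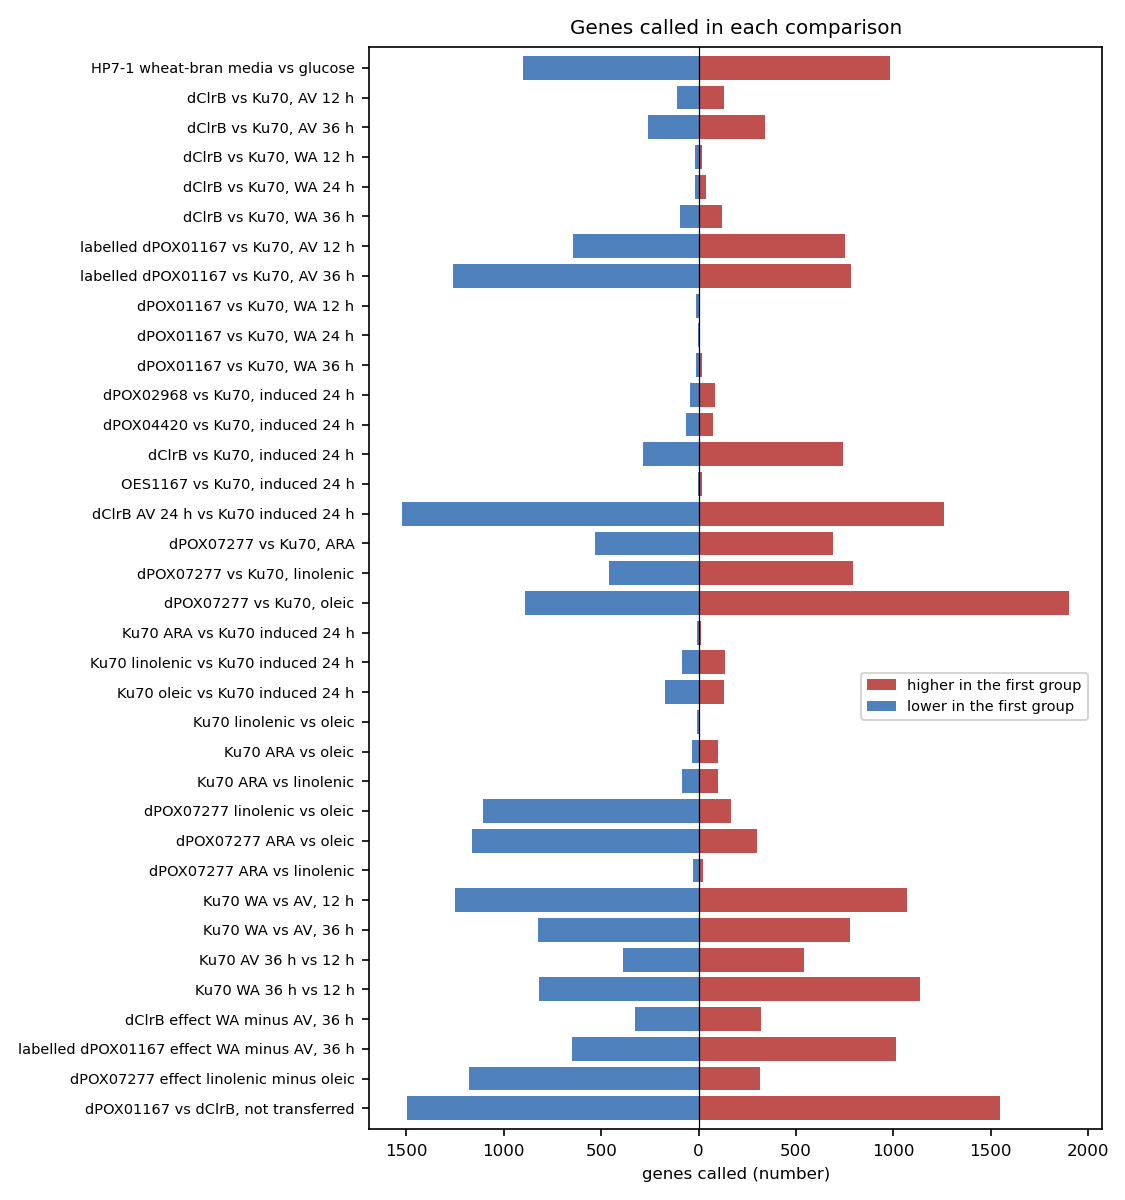
Number of genes called higher (right, red) and lower (left, blue) in the first group of each comparison (vertical axis) by edgeR. Totals run from 3 genes each way for dPOX01167 on WA at 24 h to 3044 for dPOX01167 against dClrB without transfer. The longest bars are 1901 higher for dPOX07277 on oleic acid and 1520 lower for dClrB on AV at 24 h against induced Ku70.

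Expressed as FPKM and tested with limma, several comparisons had another balance of higher and lower genes, here as the percent of calls that were higher with edgeR, with limma on log2(FPKM + 0.1) and on log2(FPKM + 1). These percentages were 52.2, 78.2 and 78.8% for HP7-1 on wheat-bran media against glucose, 54.1, 40 and 43.6% for dClrB on AV at 12 h and 54.9, 71.1 and 69.6% for dClrB on WA at 36 h. They stood at 52.9, 70.4 and 79.3% for dPOX04420, 83.3, 54.5 and 50% for OES1167 and 45.3, 26.7 and 28.2% for dClrB on AV at 24 h. Further shares were 68.1, 47.6 and 49.3% for dPOX07277 on oleic acid, 64.7, 27.8 and 42.9% for Ku70 on the oil against induced Ku70 and 43, 31.6 and 41% for Ku70 on oleic acid against induced Ku70. Shares came to 57.1, 65.2 and 68% for Ku70 on linolenic against oleic acid, 13.1, 57.2 and 52.5% for linolenic against oleic acid in dPOX07277 and 20.4, 59.9 and 57.2% for the oil against oleic acid in dPOX07277. Values reached 44.9, 61 and 62.5% for the oil against linolenic acid in dPOX07277, 48.6, 38.4 and 38.7% for Ku70 on WA against AV at 36 h and 49.4, 67.2 and 65.1% for the dClrB effect on WA minus AV. Also found were 21.2, 40.4 and 42.9% for the dPOX07277 effect on linolenic minus oleic acid. With other settings more calls became lower than higher for HP7-1 (787 higher and 918 lower with DESeq2, 923 and 942 with median-ratio size factors). So they did for the libraries labelled dPOX01167 on AV at 12 h (720 and 770, and 675 and 702). The same held in fits of the compared groups alone for dClrB on AV at 12 h (10 and 32), dClrB on WA at 36 h (58 and 78) and Ku70 on the oil against linolenic acid (75 and 116), and with a block by letter for the cultures not transferred (1348 and 1416). More became higher with the set 1 controls for dClrB on AV at 24 h (1186 and 1081), and with no filter for the oil against linolenic acid in dPOX07277 (23 and 20) and the dClrB effect on WA minus AV (344 and 300).

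In the same order, the median log2 fold change of all genes tested moved by over 0.1, being 0.13, 0.59 and 0.55 for HP7-1 on wheat-bran media against glucose, -0.02, 0.15 and 0.14 for dClrB on WA at 36 h and 0.07, 0.18 and 0.17 for the libraries labelled dPOX01167 on AV at 12 h. It was -0.01, 0.12 and 0.11 for dPOX01167 on WA at 36 h, -0.07, 0.20 and 0.19 for dPOX04420 and -0.09, 0.04 and 0.03 for induced dClrB. Medians were 0.14, -0.10 and -0.09 for dPOX07277 on oleic acid, 0.01, 0.25 and 0.23 for linolenic against oleic acid in dPOX07277 and -0.02, 0.23 and 0.21 for the oil against oleic acid in dPOX07277. It stood at -0.02, -0.16 and -0.15 for Ku70 on WA against AV at 12 h, -0.02, -0.19 and -0.18 for Ku70 on WA against AV at 36 h and -0.03, 0.22 and 0.21 for the dClrB effect on WA minus AV. Also moved were -0.04, 0.09 and 0.08 for the effect labelled dPOX01167 on WA minus AV and -0.01, 0.20 and 0.19 for the dPOX07277 effect on linolenic minus oleic acid.

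To find genes that follow the cellulase genes, levels of 8715 genes were correlated with the mean cellulase score over groups. The scores of the 33 groups fell into a lower cluster of 17 groups and a higher cluster of 16, with a gap from 5.84 to 8.27, so no r over all groups is given. In the lower cluster 27 genes had r of at least 0.8 (2853 at an unadjusted p under 0.05), among them the list members POX01166 (0.87), POX04786 (0.85) and POX05587 (0.84). POX06810 had the highest r (0.90, permutation p = 1e-05, adjusted p = 0.012; rho 0.87, permutation p = 3e-05, adjusted p = 0.035), followed by POX08015 (0.87; rho 0.82). Without the 2 groups farthest from the median score, r was 0.85 and 0.78 for these and 0.85, 0.78 and 0.80 for the list members, and no gene passed (0 by permutation, 1616 at an unadjusted p under 0.05). With median-ratio scaling 0 passed as well (2643 at an unadjusted p under 0.05). Within the time-course groups alone 27 of 27 had the same sign, 5 had r of at least 0.8 and 0 passed. In the higher cluster 0 genes passed by permutation (1272 at an unadjusted p under 0.05). Over the 6 Ku70 groups of the higher cluster 0 genes passed by exact permutation (321 at an unadjusted p under 0.05), where the smallest p that 6 groups can give is 0.00139. Over the 8 dClrB groups 565 genes passed with r of at least 0.8 and 114 with the opposite sign, by exact permutation tests, with POX01770 at r = 0.99 (exact p = 2.5e-05, adjusted p = 0.03) and rho = 1.00 (exact p = 5e-05, adjusted p = 0.036). The highest scores, of dClrB not transferred (5.84) and induced (5.17), belong to the only shallow tables among these groups. The time-course tables had scores of 2.16 to 4.2, so cellulase score and kind of table cannot be told apart here. Without the 2 farthest groups r of POX01770 was 0.98, and 0 genes passed by exact permutation (1816 at an unadjusted p under 0.05), where the smallest p that 6 groups can give is again 0.00139, so this count says nothing about stability.

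Xylanase scores of the 33 groups did not separate, and 29 genes had r of at least 0.8 with them (3646 at an unadjusted p under 0.05). Among these were 3 xylanase genes, POX06783 (0.91), POX00063 (0.89) and POX08484 (0.85), and 6 of the 9 cellulase genes, POX05570 (0.87), POX05571 (0.86), POX03641, POX04786 and POX05587 (0.82 each) and POX07535 (0.81, and 0.73 without the 2 groups farthest from the median score). POX09137 had r = 0.95 (rho 0.94, 0.94 without the 2 farthest groups) and POX01218 r = 0.93 (rho 0.93, 0.90 without). Permutation p was 1e-05 for both, the smallest that 100000 permutations can give, with adjusted p = 0.00054 for r and 0.00082 for rho. As the 33 groups are not independent of each other, these p-values do not measure chance alone. All 29 genes had the same sign within each kind of table, with POX09137 at 0.95, 0.97 and 0.89 and POX01218 at 0.99, 0.95 and 0.80 in the deep, shallow and time-course groups. Of the 29, 21, 25 and 10 had r of at least 0.8 within these kinds, and 0, 1 and 4 passed there by permutation. Over the 9 Ku70 groups 1 gene passed, POX09137 (r = 0.99, exact p = 5.5e-06, adjusted p = 0.048; rho 0.98, exact p = 5e-05, adjusted p = 0.14), and without the 2 farthest groups its r was 0.98 and 0 genes passed by exact permutation (708 at an unadjusted p under 0.05), where the smallest p that 7 groups can give is 0.000198. The dClrB groups separated into clusters of 5 and 3 groups by xylanase score, too few for a correlation.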

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

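The counts over 50 splits of the libraries were planned. So was the test of the Ku70 libraries 8 to 10 for a culture without an inducing carbon source. The other tests in this part were chosen only after the result was seen. The results below stand out because an effect differed between 2 media or 2 fatty acids by a test of the difference itself, with the log2 difference as the value.

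The effect of the clrB deletion at 36 h differed between WA and AV for 650 genes, and 1 of 50 splits, the real one, gave as many (highest other 379). These splits ignore the pairing by quantification set. The splits that part as many pairs as the real one number 16, too few for a share under 0.05, and with the sets as a block the real one gave 977 and the highest other 532. The effect was weaker on WA by 4.12 for POX05587, 3.42 for POX01166 and 2.75 for POX03641 among the cellulase genes, and by 3.06 for POX00063 among the xylanase genes. At 36 h the summed cellulase genes of Ku70 stood at 563 ± 47 CPM on WA and 12121 ± 1596 on AV, against 699 ± 132 in dClrB on AV. A fall as large as on AV thus had little room on WA, and the difference does not show that clrB acts less there.

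For the libraries labelled dPOX01167 at 36 h the difference covered 1663 genes, with 2 of 50 splits as large (highest other 1876). Of the 16 splits that part as many pairs, again too few, the real one gave 2143 with the block and the highest other 2202. The splits with 1876 and 2202 kept the real AV groups and mixed the WA libraries of both strains. The difference amounted to 9.20 for POX05587, 9.75 for POX04786, 8.77 for POX01166, 7.69 for POX05570, 5.80 for POX05571, 2.58 for POX07535 and 4.57 for POX03641. Among the xylanase genes it was 3.39 for POX00063, 5.82 for POX06783, 2.49 for POX08990 and 6.35 for POX08484. All these values rest on AV libraries whose POX01167 counts go against their label. The low cellulase level of Ku70 on WA limits this difference in the same way.

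The dPOX07277 effect differed between linolenic and oleic acid for 1493 genes, with 2 of 50 splits as large (highest other 2356). The split with 2356 kept the real groups on oleic acid and mixed the strains on linolenic acid. Since another split gave more calls than the real one, chance is left open. A count of this size does not need an effect on linolenic acid. Among the listed genes only POX05570 was called (1.39), and 0 were called by edgeR without any 1 of the 12 libraries except Ku70 library 43 (7 cellulase genes) and mutant library S on oleic acid (5). The count was 968, 932, 827 and 761 without Ku70 library 42, 44, 45 or 46, 800 and 457 without linolenic library F or S, and 653, 3086 and 984 without oleic library F, S or T of the mutant.

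The libraries labelled dPOX01167 on AV at 36 h held POX01167 at 95.6 to 207 CPM. A short gene model used in quantification sets 1 and 2 is excluded as the source in library S, which has an effective length of 1940 for this gene. Library T, with 2031, belongs to set 3, where Ku70 had no short lengths, so its length is no test of that model. Ku70 had 1733 to 1842 on WA in set 2, 2006 to 2025 in set 3, and 489 to 652 on AV in sets 1 and 2. For library F, with 1047 between these, the short model stays open. A swap with a library of another strain is excluded too, because it would leave a library without POX01167 elsewhere, and the lowest level in any other strain was 9.45 CPM. A wrong label and a culture from outside the series could both give the lowest level of 95.6 CPM and cannot be told apart, since neither leaves a partner to look for. The fall of cellulase genes in these libraries may therefore not belong to the deletion.

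The Ku70 induced libraries 8, 9 and 10 held 236 to 290 CPM of cellulase genes, against 13149 to 99559 in the other 21. They correlated with each other at 0.971 or more and with any other Ku70 induced library at 0.822 or less (log2 values across genes, which are not independent replicates). Low depth is excluded, with totals of up to 3020685 inside the range of the other shallow Ku70 libraries (2131649 to 4242956), and so is a dClrB culture, with POX01960 at 82.6 CPM or more against at most 3.49 in dClrB. In 3 of 3 the median of the genes higher on glucose lay below that of every other library (6.32 to 6.56 against 6.58 to 7.06). This direction argues against a culture in the state of HP7-1 on glucose. The reading was chosen only after the medians were known, and the nearest values lie close together, so such a state is not excluded. A culture without an inducing carbon source stays open. Although 0 of 3 libraries met both medians written down for it, with the wheat-bran genes at 4.705 to 4.794 inside the 4.599 to 5.264 of the others, that test was too wide. Its genes come from HP7-1 grown for 72 h without transfer, and a medium without carbon source, or with another that does not induce, need not raise glucose genes. No other biological explanation was tested.

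In the time-course groups, 75 to 121 genes per group stood at 0 in 1 library and at 20 CPM or more in both others, against 0 in deep groups and 0 to 8 in shallow groups. Low depth is excluded, since 20 CPM is 107 counts in the smallest time-course library. Gene models that differ between quantification sets are a candidate explanation, because 99% of the genes with several such cases (190 of 192) had the 0 in the same set each time. No listed gene was among the 284 genes (0), and they made up at most 0.937% of the calls of any of the 16 time-course comparisons that were counted.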

How the results depend on the processing

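DESeq2, controls of the same kind of table, controls without the Ku70 libraries 8 to 10, blocks by quantification set, log2(CPM + 1), the removal of genes at 0 in 1 time-course library and the use of 1 AV 12 h library were chosen after seeing the data. Limma on log2(FPKM + 1) had been the planned test and became an alternative only then. The other alternatives were planned. Of 7659 gene results recomputed, 7080 stayed on the same side of the threshold, 352 were lost, 227 were gained and 0 changed direction while called. Of 512 recomputed counts, 352 stayed within 1.5 times and 160 did not. Median-ratio size factors and no filter moved none of the 36 counts by over 1.5 times. Neither did the removal of genes at 0 in 1 time-course library for the 16 counts it applied to. Depth was lowest for HP7-1, with totals from 365937 counts. Except where fewer libraries or another spread follow from the construction of an alternative, the cause of a move was not tested.

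DESeq2 called 65 genes for dClrB on WA at 12 h (34 with edgeR) and 115 at 24 h (59). For the libraries labelled dPOX01167 it called 38 on WA at 12 h (17), 24 at 24 h (6) and 55 at 36 h (29). It called 415 for dPOX02968 (129), 315 for dPOX04420 (138) and 120 for OES1167 (18). Against the induced Ku70 libraries it called 319 for arachidonic acid oil (17), 640 for linolenic acid (220) and 659 for oleic acid (300). Within Ku70 it called 107 between linolenic and oleic acid (14), 240 between the oil and oleic acid (131) and 321 between the oil and linolenic acid (188). Within dPOX07277 it called 117 between the oil and linolenic acid (49).

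With limma on log2(FPKM + 0.1), OES1167 had 11 calls, Ku70 on linolenic against oleic acid 23, and the difference of the dPOX07277 effect between these acids 946 (1493 with edgeR). With limma on log2(FPKM + 1), these were 6, 25 and 986. There dClrB on WA had 53 calls at 12 h and 90 at 24 h, the libraries labelled dPOX01167 on WA 10 at 24 h and 49 at 36 h, dPOX04420 217, dClrB on AV at 24 h 1733 (2781 with edgeR), and Ku70 on oleic acid against the induced libraries 188.

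Fits of the compared groups alone, with fewer libraries behind the spread, called 42 genes for dClrB on AV at 12 h (242 in the shared fit). On WA they called 3 at 12 h, 19 at 24 h and 136 at 36 h (215). For the libraries labelled dPOX01167 they called 112 on AV at 12 h (1396), and 0, 0 and 4 on WA at 12, 24 and 36 h. They called 172 for Ku70 on linolenic against oleic acid. For dPOX07277 they called 0 for linolenic against oleic acid (1274), 0 for the oil against oleic acid (1461) and 146 for the oil against linolenic acid.

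The choice of Ku70 controls moved every 24 h comparison except those of dClrB. With the 12 controls of the same kind of table there were 458 calls for dPOX02968, 457 for dPOX04420, 84 for OES1167, and 417, 714 and 790 for Ku70 on the oil, linolenic and oleic acid. Without the Ku70 libraries 8 to 10 these were 221, 275, 84, 125, 460 and 597, and with both choices dPOX04420 had 1001. With only the 3 controls of set 1 they were 1196, 1487, 1828, 1198, 1702 and 1522, and 55 of 134 results of single genes were gained and 0 lost.

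A replicate block by quantification set, which pairs the time-course libraries, called 376 genes for dClrB on AV at 12 h, 71, 108 and 323 on WA at 12, 24 and 36 h, and 977 for the difference of the dClrB effect between media (650 unblocked). For the libraries labelled dPOX01167 on WA it called 34, 15 and 49. It moved no other time-course count by over 1.5 times. Outside the time course, letters correlated between -0.16 and 0.55, except in the pair of dPOX07277 groups above. There the letters paired the libraries with 3 of 3 best with their own letter, and the blocked count was 48 against 49. A replicate block by letter with the controls of set 1 called 1185 genes for dPOX02968, 1488 for dPOX04420, 646 for dClrB induced, 1820 for OES1167 and 1555 for dClrB on AV at 24 h, where letters do not pair the libraries. With these controls unblocked the counts were 1196, 1487, 691, 1828 and 2267.

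Leaving out each library in turn gave 1240 to 1843 calls for HP7-1 and 442 to 1029 for dClrB induced. For dClrB it gave 138 to 280 on AV at 12 h, 18 to 41 on WA at 12 h, 28 to 45 at 24 h and 112 to 245 at 36 h. For the libraries labelled dPOX01167 it gave 847 to 2088 on AV at 12 h, 9 to 30 on WA at 12 h and 11 to 27 at 36 h. It gave 27 to 47 for dPOX02968, 9 to 54 for dPOX04420 and 1 in each case for OES1167. Leaving out a library of the other group was done only for groups of 3, so the 24 controls were not left out singly. Ku70 against the induced libraries had 4 to 5 on the oil, 51 to 106 on linolenic acid and 39 to 54 on oleic acid. Within Ku70 there were 4 to 18 between linolenic and oleic acid, 20 to 262 between the oil and oleic acid, and 44 to 348 between the oil and linolenic acid. Within dPOX07277 these were 362 to 2672, 592 to 2634 and 12 to 27, and the difference of its effect between linolenic and oleic acid had 457 to 3086.

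Of genes correlated with the cellulase score, the 27 of the lower cluster became 0 with median-ratio scaling, 5 with every library as a point, 0 without the 2 groups farthest from the median and 69 without HP7-1. The 0 of the higher cluster became 3, 40 and, without HP7-1, 9. The 0 over the Ku70 groups of the higher cluster became 109 with every library as a point. The 565 over dClrB groups became 276 with median-ratio scaling, 330 with every library and 0 without the 2, where 6 groups can give no p under 0.00139. For the xylanase score, 1 gene over Ku70 groups became 61 with every library as a point, 0 without the 2 farthest groups and 0 with log2(CPM + 1).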

Other observations

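The tests of POX01960, POX05007, POX01924 and POX01925 and the splits without the Ku70 libraries 8 to 10 below were chosen only after the result was seen, and the counts over other splits were planned.

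POX01960 stood at 3.49 CPM or less in all 24 dClrB libraries and at 13.3 CPM or more in the other 90. It was the only gene with that pattern (1 gene), which is consistent with POX01960 being the deleted clrB locus, a hypothesis here since the files name no locus for clrB. In the libraries labelled dPOX01167 on AV at 36 h it lay at 13.3 to 15.4 CPM, against 216 to 276 in Ku70. POX05007 was at 0.211 CPM or less in the 3 OES1167 libraries and at 4.39 or more in all others, again as the only gene (1 gene). The overexpression construct may have removed or silenced it, which libraries of 1 strain cannot show. POX01924 (1.55 to 2.25 CPM) and POX01925 (at most 0.143 CPM) were the 2 genes far below all other libraries in dPOX02968, where the others had at least 174 and 11.8 CPM. Both may have been lost together with POX02968, and with 1 strain this stays open.

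POX05569 reached 2412 to 6835 CPM in dClrB on the inducing carbon source and 659 to 2258 CPM in HP7-1 on wheat-bran media, against at most 51.9 CPM elsewhere. POX01582 was at 73.2 to 105 CPM in HP7-1 and at 0 in all 108 other libraries. POX03097 was at 0 in the 3 Ku70 libraries on AV at 36 h and at 4.45 CPM or more in every other library. POX01168, which follows POX01167 in the numbering of IDs, stood at 19.1 to 65.2 CPM in the libraries labelled dPOX01167 on WA and at 1.51 to 10 CPM in Ku70 on WA. These genes were picked after their values were seen.

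Other splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. In each of the following, 1 of the 10 splits, the real one, gave the most calls, here with the highest other in parentheses. HP7-1 had 1880 (0). The clrB deletion had 242 (135) and 601 (8) on AV at 12 and 36 h, and 34 (2), 59 (1) and 215 (1) on WA at 12, 24 and 36 h. The libraries labelled dPOX01167 had 1396 (532) and 2044 (30) on AV, and 17 (6), 6 (0) and 29 (1) on WA. The cultures not transferred had 3044 (0). The POX07277 deletion had 1223 (0) on arachidonic acid oil, 1252 (0) on linolenic acid and 2790 (944) on oleic acid. Within Ku70, linolenic against oleic acid had 14 (0), the oil against oleic acid 131 (20) and the oil against linolenic acid 188 (26). Within dPOX07277 these were 1274 (1246), 1461 (1181) and 49 (0). WA against AV in Ku70 had 2319 (0) at 12 h and 1601 (1) at 36 h, and 36 h against 12 h had 928 (1) on AV and 1956 (1) on WA.

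For the comparisons with the 24 Ku70 induced libraries 50 of 2925 splits were drawn, and 50 of 2024 without the Ku70 libraries 8 to 10. Splits that set Ku70 libraries against other Ku70 libraries called up to 2225 genes with all 24 (libraries 8, 9 and 10 against the rest) and up to 651 without these (15, 16 and 17 against the rest). Such splits follow a structure of the Ku70 libraries, so for a real count below theirs the share depends on how many of them were drawn, and chance is left open. For dClrB on AV at 24 h the real split gave 2781 calls (1 of 50 splits as large, highest other 826). Without libraries 8 to 10 it gave 2826 (1 of 50, highest other 402). The mutant libraries are the only time-course tables in that comparison, so the real split also follows the kind of table. Its count therefore cannot speak for the strain. For dClrB on the inducing carbon source the real split gave the most calls without libraries 8 to 10 (1132, 1 of 50, highest other 178). That setting was chosen after the data were seen. With all 24 there were 1026 (2 of 50, highest other 2225), so chance is left open.

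Chance is left open for the other comparisons as well, given here with all 24 and then without libraries 8 to 10. These were dPOX02968 with 129 (2 of 50, highest other 681) and 221 (2 of 50, highest other 651), dPOX04420 with 138 (1 of 50, highest other 4) and 275 (3 of 50, highest other 444), and OES1167 with 18 (3 of 50, highest other 337) and 84 (1 of 50, highest other 9). Ku70 had 17 (4 of 50, highest other 391) and 125 (1 of 50, highest other 8) on the oil, 220 (1 of 50, highest other 15) and 460 (1 of 50, highest other 393) on linolenic acid, and 300 (3 of 50, highest other 644) and 597 (1 of 50, highest other 274) on oleic acid. The splits with 444 and 393 both set the Ku70 libraries 17, 18 and 19 against the rest.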
